A study of Mus musculus with 148 samples.

How the data were processed

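RNA-seq libraries of skeletal elements from mouse embryos of the FVB/NJ strain at embryonic stage E15.5 were analysed. Per the labels' protocols, the phalanges of a digit were pooled, the metapodials were collected separately, left and right sides were pooled, and elements were stripped of soft tissue before RNA was extracted from the 3 digits I, III and V of fore- and hindlimbs. The labels list 148 samples, which the authors' table of samples joins in pairs of sequencing runs to 74 files of values, each covering 2 runs of a library. How the runs were combined is not stated in the sources used here. Of these, 72 libraries had been made with a standard kit whose name the sources used here do not give, and 2 with the KAPA kit. The authors aligned reads with STAR 2.7.1 to the mm10 build and counted them with RSEM 1.3.3, per the submitters' processing notes, which also name DESeq2 1.36.0. The deposited values used here were the column of expected count per gene that RSEM writes, which is not normalized; 68.5% of the expected counts were whole numbers. The files held 56691 gene IDs, of which 52073 had a symbol in GENCODE release M21 on mm10 (99.84% of all counts), and 39480 had a count in any library. Genes were matched by ID without its version, and positions were taken from the same annotation.

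Libraries were grouped by their labels into 12 groups of element, limb and digit with 6 embryos each. The replicate number, which the labels share across the elements of an embryo, was used as a block, because the 12 libraries of a number were regions of the same animal. The pairing was checked on the values left after removing group means: libraries of the same number had a mean correlation of 0.08 over 396 pairs and those of different numbers -0.015, 60 of the 72 libraries were nearest to others of their own number, and 34.1% of the pairs of a number were above 0.1, so the pairing rests on the labels. No 2 libraries of a group were copies (lowest chi-square per gene 17.3 over 180 pairs).

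Expected counts were rounded, filtered with filterByExpr on the 12 groups, which left 21753 genes, and scaled by TMM factors (0.744 to 1.07). A model with the 12 groups and the replicate block was fitted to all 72 libraries (common dispersion 0.228, 55 residual degrees of freedom). Each comparison was a contrast of this model, tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, two-sided, and genes with an adjusted p under 0.05 were called. There were 13 comparisons: 4 main ones (hand against foot, phalanges against metapodials, digit I and digit V against digit III), 6 of hand against foot in matched elements, and 3 differences of differences (limb by element, limb by digit I and element by digit I). Log2 fold changes are those of the fit with their standard errors (SE), taken as the fold change divided by the square root of the F statistic. CPM were computed by edgeR with the scaled totals and are given as the mean and SD over 6 embryos; in the main comparisons each embryo's value was the mean of its libraries. Embryos in a direction were counted from each embryo's contrast of the groups on the log scale of CPM, not from these means. The count and the means can disagree. Alx4 was counted as lower in the hand in 6 of 6 embryos, with means of 9.515 CPM in the hand and 7.316 CPM in the foot.

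The 22 gene lists, fixed before the data were examined together with the comparisons, the rule for naming genes and 15 of the 19 alternative settings, were limb identity (forelimb and hindlimb), HoxA and HoxD genes, anterior and posterior limb genes, cartilage matrix, hypertrophic chondrocyte, osteoblast and perichondrium, joint interzone, digit tip and nail, the hedgehog, BMP, WNT and FGF pathways, proliferation, and markers of skeletal muscle, tendon, epidermis, endothelium, erythroid cells, macrophages and osteoclasts, and nerve. Lists with at least 4 tested genes were compared with all other genes by limma's camera on log2 CPM with a prior count of 2 and a correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of a comparison. Hoxd10, Hoxd11 and Hoxd12 are members of both the HoxA and HoxD list and the posterior list. List members were also counted after adjustment over the list alone. With group labels reassigned within embryos, the preset correlation still called a median of 13 lists, so a list call that the estimated correlation did not keep is weak.

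Named genes were, in each main comparison, the 8 with the largest rise and the 8 with the largest fall among called genes with a symbol, a mean of at least 1 CPM and the same direction in 6 of 6 embryos, leaving out predicted gene models and clone names, and up to 3 genes of each list with the smallest adjusted p. The top 3 each way were named in the matched comparisons, the top 5 each way in the differences of differences, and 17 genes of limb identity, HoxA and HoxD, cartilage and joint throughout. Only some of the genes that this rule names are printed below. Of these 17, Hoxc9 did not pass the filter on low counts. List members named in the differences of differences, and other genes beyond the rule, were chosen after their values were seen.

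The alternatives were DESeq2's Wald test with its own size factors, limma-voom, RLE size factors, no filter on low counts, a filter of at least 1 CPM in at least 36 libraries, 3 covariates (mean log2 CPM of the muscle, epidermis and erythroid markers), no replicate block, counts summed per embryo and level, only the libraries of the 2 groups compared, and leaving out each embryo in turn. A further 4 were chosen after seeing the data: leaving out the 3 libraries with the fewest genes detected, leaving out the foot phalanges libraries of digits I and V of replicate 5, leaving out 8 libraries that stood apart (these 5 and 3 with high epidermis markers), and limma-voom with library quality weights. For each comparison the group labels were reassigned within embryos 20 times with a fixed seed and the genes called were counted again; in the matched comparisons hand and foot were exchanged within embryos.

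The calls were tested on simulated data with 200 genes changed, without differences between embryos or libraries that stand apart. Between hand and foot, edgeR recovered 47.6%, 79.1% and 95.5% of genes changed by a log2 fold of 0.5, 1 and 2, and called 0.071% of unchanged genes; limma-voom recovered 42.9%, 76.1% and 98.5%, and DESeq2 54% (0.236% of unchanged genes called), 83.6% and 100%. In the matched digit III phalanges edgeR recovered 14.9%, 34.3% and 72.3%, so changes of a log2 fold of 1 or less were mostly missed there. The changed list was called and 0 of 20 unchanged lists were. Simulated genes were drawn independently of each other, so this does not test lists whose genes vary together.

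R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. The KAPA libraries were left out of the fit, because each had 1 library per element, and were compared with the standard-kit libraries of the same embryo by their values alone. Open chromatin data of the study were not analysed here.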

Results

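Gene expression was measured by RNA-seq in skeletal elements of the mouse autopod, the most distal limb segment, at embryonic stage E15.5 in the FVB/NJ strain. The series title places the data in work on the evolution of the autopod skeleton, and its design text names differential expression among developing elements as the aim. The comparisons asked which genes set limbs, elements and digits apart, and whether the limb difference varied with element or digit. The phalanges and the metapodial (metacarpal in the hand, metatarsal in the foot) of digits I, III and V had been dissected from fore- and hindlimbs of 6 embryos. This gave 12 groups of 6 libraries, 1 per embryo, or 72 libraries. The 12 libraries of an embryo came from 1 animal, so comparisons were made within embryos. A further 2 libraries of digit III phalanges, 1 of the hand and 1 of the foot, had been made with another kit (KAPA). Total expected counts ran from 18117001 to 44619471 per standard-kit library. In these libraries 17610 to 24180 genes had a count, with a median of 23093. The first principal component (15% of the variance) set apart metacarpal I replicates 2 and 5 and metatarsal I replicate 5, and the next (9.5%) ran between phalanges and metapodials.

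**Figure D1:**
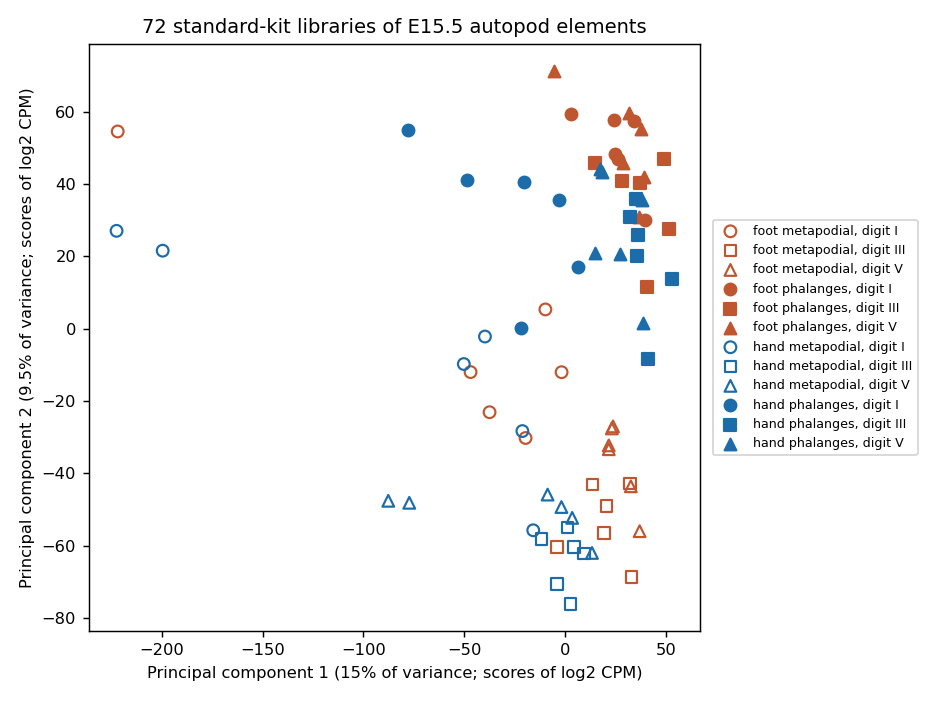
Scores of the 72 standard-kit libraries on the first and second principal components of log2 CPM (15% and 9.5% of the variance); colour gives the limb, filled or open symbols the element and shape the digit. Phalanges lie above 0 on the second axis in all libraries but 1, and 3 open circles of digit I metapodials lie at -199.63 or below on the first axis.

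Hand and foot elements carried the known limb identity genes. Tbx5 (ENSMUSG00000018263, chromosome 5, 119832668 to 119885219), the T-box factor required for forelimb formation, stood at 99.2 ± 11.8 CPM in the hand and 3.82 ± 1.03 CPM in the foot (SD of 6 embryo means), a log2 fold change of 5.14 ± 0.13 (SE; adjusted p = 1.83e-40). Pitx1 (ENSMUSG00000021506, chromosome 13, 55825051 to 55836192), the homeobox gene that specifies the hindlimb, stood at 1.66 ± 0.47 CPM in the hand and 71.7 ± 12.4 CPM in the foot (log2 -5.63 ± 0.19, adjusted p = 3.87e-34). Its target Tbx4 (ENSMUSG00000000094, chromosome 11, 85886422 to 85916097) was present in both limbs, at 43.4 ± 4.14 CPM in the hand and 150 ± 9.36 CPM in the foot (log2 -1.82 ± 0.06, adjusted p = 3.67e-33). Each of these 3 differences had the same direction in 6 of 6 embryos and in each of the 6 matched pairs of elements. Beyond them, Spon2 (log2 2.85 ± 0.26) and Enpp6 (2.98 ± 0.40) were higher in the hand. So were Msmp (3.84 ± 3.25 against 0.186 ± 0.238 CPM) and the cartilage-secreted protein gene Ucma (2.99 ± 2.84 against 0.472 ± 0.578 CPM), whose folds are not given because a foot group had 3 counts or fewer. A2m (-2.09 ± 0.27), the glypican gene Gpc5 (-1.87 ± 0.27) and Gpr83 (-2.68 ± 0.32) were lower, again in 6 of 6 embryos. Gpr83 was called in metapodials (adjusted p = 1.92e-12) but not in phalanges (adjusted p = 0.974). Gpc5 was called in digit I (adjusted p = 1.03e-08) but not in digits III and V (adjusted p = 0.0666).

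By gene list, the hand had less RNA of dividing cells, while the higher level of cartilage matrix genes was not called with an estimated correlation. Of the 22 cartilage matrix genes, 19 were higher in the hand and 3 did not pass, with the same counts adjusted over the list alone. Epyc rose by 1.28 ± 0.14 and Scrg1 by 0.99 ± 0.10 on the log2 scale. Col2a1, the main cartilage collagen, had 5924 ± 1150 CPM in the hand and 5968 ± 1975 CPM in the foot. Sox9 had 685 ± 48.7 and 692 ± 69 CPM. The cartilage list had an adjusted p = 7.1e-09 at the preset correlation of camera and an adjusted p = 0.192 with an estimated correlation. Of 16 proliferation genes, 15 were lower in the hand, 16 when adjusted over the list alone (adjusted p = 4.41e-17, and adjusted p = 0.0012 with an estimated correlation). Among them were the mitotic kinase gene Plk1 (-0.61 ± 0.07) and the replication helicase gene Mcm5 (-0.49 ± 0.04). Of 18 joint interzone genes, 9 were higher and 3 lower, the same counts as adjusted over the list alone (adjusted p = 0.0372, and adjusted p = 0.38 with an estimated correlation). Wnt4 (1.09 ± 0.11) and Trps1 (0.48 ± 0.06) were higher and Sfrp2 (-0.69 ± 0.08) was lower. Of 8 tendon genes, 6 were higher (7 adjusted over the list alone) and 1 lower (adjusted p = 0.00126, and adjusted p = 0.0654 with an estimated correlation). The tendon transcription factor genes Scx (0.58 ± 0.08) and Mkx (0.62 ± 0.08) were among those higher. All 4 tested hindlimb identity genes were lower, also adjusted over the list alone (adjusted p = 3.77e-09, and adjusted p = 9.64e-07 with an estimated correlation). Of these, Hoxc10 and Hoxc11 lay under 1 CPM on average in both limbs and lost the call over all elements under other settings. Their RNA was found in metatarsal V, where Hoxc10 had 1.498 ± 0.47 CPM against 0.0092 ± 0.022 CPM in metacarpal V (adjusted p = 0.00171) and Hoxc11 0.85 ± 0.32 against 0.0045 ± 0.011 CPM (adjusted p = 0.00479), both in 6 of 6 embryos. In digit I their limb difference was not that of digits III and V (adjusted p = 0.0187 for Hoxc10 and adjusted p = 0.00627 for Hoxc11), calls lost with the marker covariates and without replicate 2. There the hand means lay above those of the foot, without a call (adjusted p = 0.301 and adjusted p = 0.281). Hoxc10 had 0.347 ± 0.542 against 0.0875 ± 0.0909 CPM in phalanges and 0.156 ± 0.227 against 0.0309 ± 0.0757 CPM in metapodials. Hoxc11 had 0.179 ± 0.359 against 0.0476 ± 0.104 CPM and 0.138 ± 0.298 against 0.0044 ± 0.011 CPM. Forelimb identity had a single tested gene, Tbx5.

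Several signalling lists moved in both directions between the limbs. Of 20 WNT genes, 8 were higher and 5 lower (10 and 6 adjusted over the list alone; adjusted p = 0.106). The antagonists Sfrp5 (1.92 ± 0.16) and Wif1 (0.98 ± 0.08) were higher in the hand. Of 11 hedgehog response genes, 4 were higher and 5 lower (5 and 5 adjusted over the list alone; adjusted p = 0.874). Ihh, the hedgehog ligand of prehypertrophic chondrocytes, was lower (-0.85 ± 0.12). Of 14 FGF pathway genes, 2 were higher and 2 lower, with the same counts adjusted over the list alone (adjusted p = 0.122). Fgf10 was lower (-1.20 ± 0.09). Of 11 HoxA and HoxD genes, 2 were higher and 5 lower, likewise adjusted over the list alone (adjusted p = 0.185), among them Hoxa13 (-0.39 ± 0.04). Of 18 BMP genes, 2 were higher and 4 lower, with the same counts adjusted over the list alone (adjusted p = 0.287), among them Bmp3 (-0.71 ± 0.10).

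Markers of other tissues differed between the limbs as well. Epidermis markers were higher in the hand in 5 of 12 genes, also adjusted over the list alone (adjusted p = 0.0372, and adjusted p = 0.545 with an estimated correlation). Krt15 had 60.5 ± 100 CPM in the hand and 6.36 ± 1.96 CPM in the foot. Skeletal muscle markers were higher in 4 of 15 genes (adjusted p = 0.0836), macrophage and osteoclast markers in 5 of 10 (adjusted p = 0.0373, and adjusted p = 0.286 with an estimated correlation) and nerve markers in 1 of 8, in each list the same count as adjusted over the list alone. The osteoclast protease gene Ctsk was higher by 0.49 ± 0.07. Endothelial markers were lower in 5 of 8 genes, 6 adjusted over the list alone (adjusted p = 0.000689, and adjusted p = 0.142 with an estimated correlation). Kdr had a log2 fold change of -0.57 ± 0.10. In total 6829 of 21753 tested genes differed, 3633 higher and 3196 lower in the hand.

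**Figure D2:**
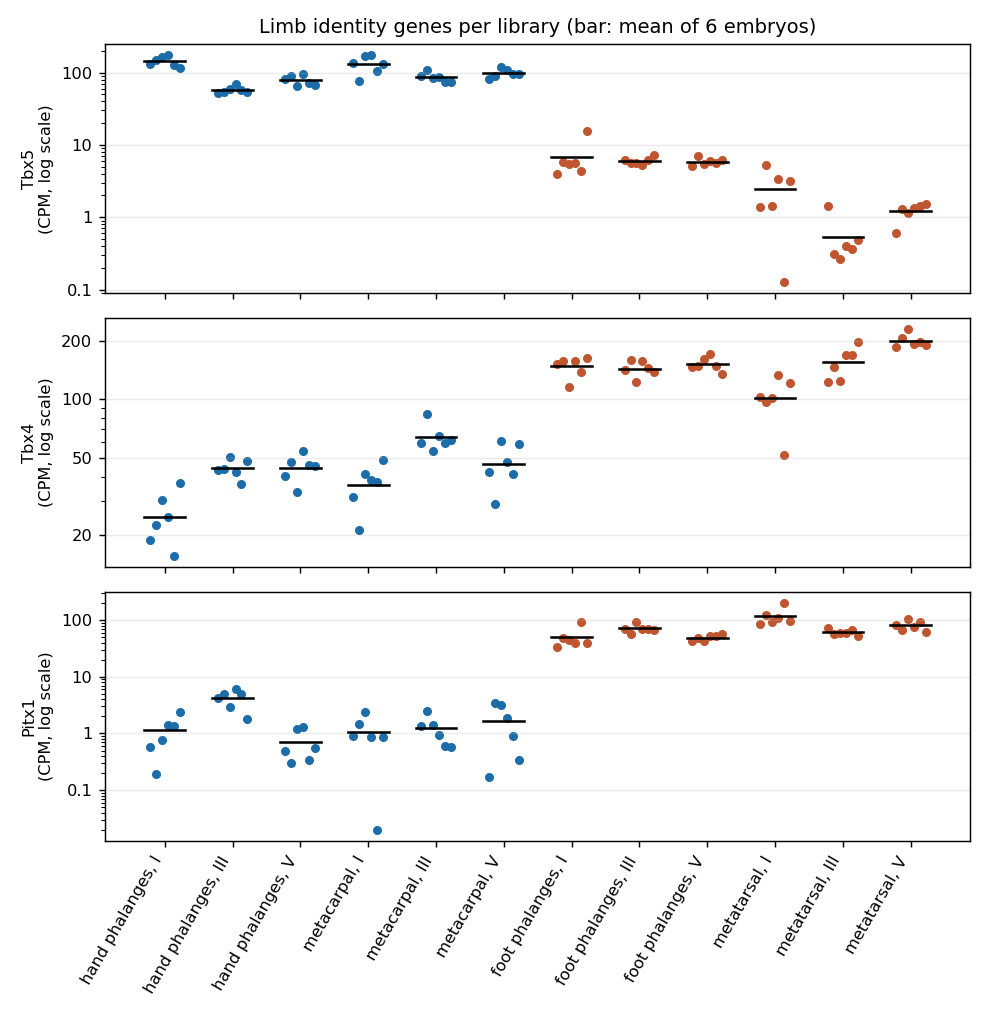
CPM of Tbx5, Tbx4 and Pitx1 in each of the 72 standard-kit libraries (log axis, lowest drawn level 0.02), by element and digit; a bar marks the mean of 6 embryos, blue is hand and orange foot. Tbx5 is higher in every hand group than in every foot group, and Pitx1 and Tbx4 are lower.

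Phalanges and metapodials differed in single homeobox genes and in cartilage matrix genes. Evx1 (ENSMUSG00000005503, chromosome 6, 52313498 to 52318378), a homeobox gene beside the HoxA cluster, had 4.41 ± 0.78 CPM in phalanges and 0.043 ± 0.025 CPM in metapodials (adjusted p = 4.87e-25, higher in 6 of 6 embryos). The homeobox gene Msx1 (ENSMUSG00000048450, chromosome 5, 37820485 to 37824583), known from the digit tip, had 721 ± 72.6 and 123 ± 30.9 CPM (log2 2.88 ± 0.08, adjusted p = 5.01e-40). Dbx2 (5.86 ± 0.18), Tfap2b (5.58 ± 0.19), Sp9 (5.54 ± 0.26) and Hottip (4.89 ± 0.23), a long noncoding RNA from the end of the HoxA cluster, were also higher in phalanges of 6 of 6 embryos. In metapodials, Col2a1 had 8710 ± 1928 CPM against 3182 ± 735 CPM in phalanges (-1.33 ± 0.11, adjusted p = 6.91e-16). Lhx8 (-5.04 ± 0.40), Clec3a (-3.79 ± 0.36) and C1qtnf3 (-3.55 ± 0.15) were lower in phalanges. Evx1 and Evx1os overlap on opposite strands and Hottip lies beside a coding gene, and whether the counting used strand is not given in the sources used here, so the values of all 3 are uncertain.

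The lists followed the same axis. All 22 cartilage matrix genes were lower in phalanges, also adjusted over the list alone (adjusted p = 2.11e-31, and adjusted p = 0.0069 with an estimated correlation). Comp changed by -3.52 ± 0.17 and Cnmd by -2.63 ± 0.13. Of 13 tested digit tip and nail genes, 8 were higher (9 adjusted over the list alone) and 1 lower (adjusted p = 3.1e-06, and adjusted p = 0.0173 with an estimated correlation). Msx2 (3.24 ± 0.12) and Wnt5a (2.46 ± 0.08) were among those higher. Of 11 HoxA and HoxD genes, 7 were higher and none lower, with the same count adjusted over the list alone (adjusted p = 0.00104, and adjusted p = 0.0173 with an estimated correlation). They included Hoxa13 (1.35 ± 0.04) and Hoxa9 (0.59 ± 0.05). Posterior limb genes were higher in 6 of 7, also adjusted over the list alone (Tbx3 1.62 ± 0.13; adjusted p = 0.00113, and adjusted p = 0.0274 with an estimated correlation). Of the members counted as higher in this list and in the HoxA and HoxD list, Hoxd10 went from a log2 of 0.66 to 0.34 and lost its call without the foot phalanges libraries of digits I and V of replicate 5. With counts summed per embryo, Hoxd10 (-0.003) and Hoxd11 (0.008) both lost their calls. Anterior limb genes were higher in 5 of 9 and lower in 2, also adjusted over the list alone (adjusted p = 0.00438, and adjusted p = 0.0173 with an estimated correlation). Alx4 (4.50 ± 0.31) was higher and Pax9 (-2.45 ± 0.25) was lower. Of 20 WNT genes, 11 were higher and 6 lower, also adjusted over the list alone (adjusted p = 0.00439, and adjusted p = 0.0463 with an estimated correlation). Examples were Lef1 (1.98 ± 0.11) and Sfrp5 (-2.64 ± 0.16). Of 16 hypertrophic chondrocyte genes, 6 were higher and 2 lower, also adjusted over the list alone (adjusted p = 0.0281, and adjusted p = 0.47 with an estimated correlation). Mef2c (0.70 ± 0.05) and Pth1r (0.50 ± 0.06) were higher, and Col10a1 (adjusted p = 0.13) and Ihh (adjusted p = 0.131) did not pass.

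Muscle markers were lower in phalanges in 14 of 15 genes, also adjusted over the list alone (adjusted p = 2.59e-13, and adjusted p = 0.0201 with an estimated correlation). Myod1 had 0.26 ± 0.17 CPM in phalanges and 4.38 ± 3.16 CPM in metapodials. Epidermis markers were higher in 9 of 12 genes (10 adjusted over the list alone; adjusted p = 0.16), and erythroid markers lower in 6 of 8 (7 adjusted over the list alone; adjusted p = 0.07). In all, 9301 genes differed, 4558 higher and 4743 lower in phalanges. With the mean levels of the muscle, epidermis and erythroid markers as covariates, 2537 genes passed.

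Digit I had little RNA of 3 HoxD genes that were well expressed in digit III. Hoxd11 (ENSMUSG00000042499, chromosome 2, 74679557 to 74687016) had 2.43 ± 3.54 CPM in digit I and 42.7 ± 3.66 CPM in digit III (log2 -5.23 ± 0.32, adjusted p = 6.7e-20). Without the foot phalanges library of replicate 5 labelled digit I, the digit I mean of Hoxd11 was 0.905 ± 0.403 CPM, that of Hoxd10 went from 2.59 ± 4.06 to 1.31 ± 0.973 CPM and that of Hoxd12 from 7.17 ± 13.8 to 1.52 ± 0.351 CPM. The neighbours Hoxd10 (ENSMUSG00000050368, chromosome 2, 74691924 to 74695105; -4.89 ± 0.35, adjusted p = 2.02e-17) and Hoxd12 (ENSMUSG00000001823, chromosome 2, 74675013 to 74677705; -4.76 ± 0.33, adjusted p = 3.15e-18) were lower as well, all 3 in 6 of 6 embryos. Hoxd13 had 191 ± 28.2 CPM in digit I and 205 ± 24.1 CPM in digit III (-0.16 ± 0.06, adjusted p = 0.0393), a call lost under 9 other settings. Sp9 (4.71 ± 0.31), a zinc finger gene, and Hoxa13 (0.75 ± 0.05) were higher in digit I of 6 of 6 embryos. The sphingomyelinase gene Smpd3, which acts in skeletal mineralization, was lower (7.23 ± 4.79 against 87.0 ± 33.2 CPM). Ostn, a secreted factor of bone and muscle, had 2.81 ± 1.42 against 10.7 ± 2.62 CPM (adjusted p = 1.12e-11). Amy2a2, Amy2a3 and Amy2a4, near-identical copies, had equal values and are uncertain. Exosc6 (10.0 ± 13 CPM in digit I) varied too widely between libraries to weigh, and its call was lost without replicate 5.

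**Figure D3:**
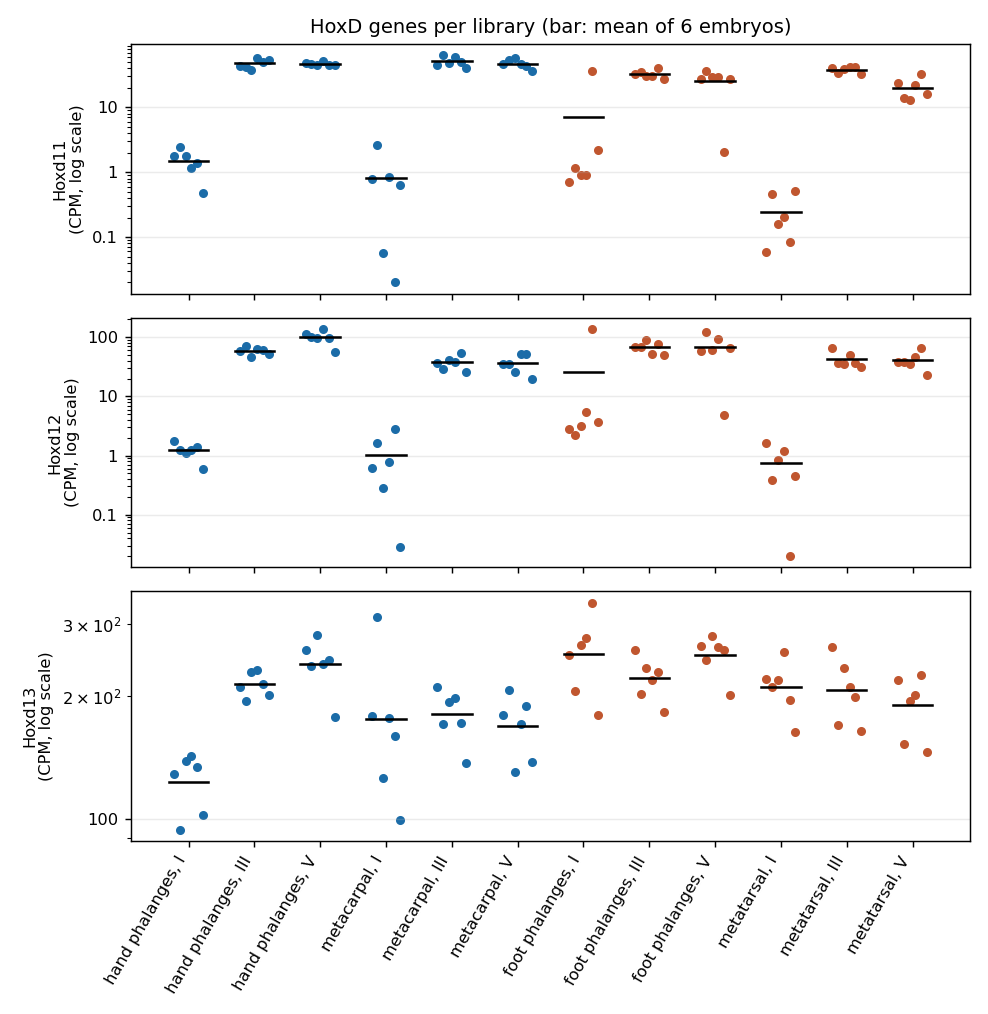
CPM of Hoxd11, Hoxd12 and Hoxd13 in each of the 72 standard-kit libraries (log axis, lowest drawn level 0.02), by element and digit; a bar marks the mean of 6 embryos, blue is hand and orange foot. Hoxd11 and Hoxd12 are low in the digit I groups and Hoxd13 is not; in replicate 5 the foot phalanges library labelled digit I has 37.0 CPM of Hoxd11 and the one labelled digit V 2.09 CPM.

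In digit I most genes of 3 skeletal lists were lower, but with an estimated correlation only the osteoblast list was called. Of 16 hypertrophic chondrocyte genes, 10 were lower and none higher (11 lower adjusted over the list alone; adjusted p = 5.5e-06, and adjusted p = 0.0687 with an estimated correlation). Col10a1, the collagen of hypertrophic cartilage (ENSMUSG00000039462, chromosome 10, 34389981 to 34397085), had 15.8 ± 3.86 against 84.5 ± 52.6 CPM (-2.18 ± 0.27). The channel gene Panx3 was lower too (-2.52 ± 0.21). Cartilage matrix genes were lower in 17 and higher in 2 of 22, also adjusted over the list alone (adjusted p = 2.97e-06, and adjusted p = 0.302 with an estimated correlation). Comp was at -2.15 ± 0.20. Osteoblast and perichondrium genes were lower in 8 (9 adjusted over the list alone) and higher in 1 of 12 (adjusted p = 0.000131, and adjusted p = 0.0491 with an estimated correlation). Col1a1 was at -1.05 ± 0.08. Of 7 posterior limb genes, 5 were lower and 2 higher, also adjusted over the list alone (adjusted p = 0.00108, and adjusted p = 0.0687 with an estimated correlation). Of 14 FGF pathway genes, 7 were lower, also adjusted over the list alone (adjusted p = 0.00959, and adjusted p = 0.302 with an estimated correlation). Fgfr3 was at -0.77 ± 0.10.

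Blood and skin markers were higher in digit I, though neither list was called with an estimated correlation. All 8 erythroid markers were higher, also adjusted over the list alone (adjusted p = 0.000152, and adjusted p = 0.302 with an estimated correlation). The haemoglobin gene Hba-a1 had 7017 ± 7250 against 1596 ± 1473 CPM; haemoglobin paralogs share reads and are uncertain singly. Epidermis markers were higher in 7 of 12 genes, also adjusted over the list alone (adjusted p = 0.0224, and adjusted p = 0.559 with an estimated correlation). Endothelial markers were lower in 5 of 8, also adjusted over the list alone (adjusted p = 0.0416, and adjusted p = 0.44 with an estimated correlation). The mast cell protease genes Cma1 (2.80 ± 0.37), Tpsb2 (3.01 ± 0.45) and Tpsab1 (2.60 ± 0.45) were among the genes higher in digit I. In all, 9066 genes differed, 4443 higher and 4623 lower in digit I. With the 3 marker covariates 4574 passed.

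Digit V carried more posterior limb RNA and less cartilage RNA than digit III. Tbx3 (ENSMUSG00000018604, chromosome 5, 119670669 to 119684724), a T-box gene of the posterior limb bud, had 19.5 ± 2.34 CPM in digit V and 6.86 ± 1.61 CPM in digit III (log2 2.03 ± 0.16, adjusted p = 3.02e-15, 6 of 6 embryos). The posterior factor gene Hand2 (1.03 ± 0.15), Tbx2 (0.80 ± 0.12) and the homeobox gene Shox2 (2.17 ± 0.22) were higher too. Posterior limb genes were thus higher in 3 of 7, also adjusted over the list alone (adjusted p = 0.000137, and adjusted p = 0.0167 with an estimated correlation). Hoxd10, Hoxd11 and Hoxd12 did not pass (Hoxd11 35.1 ± 3.11 against 42.7 ± 3.66 CPM). Hoxd10 (-0.47 ± 0.28) and Hoxd11 (-0.34 ± 0.26) were lower in 6 of 6 embryos, while Hoxd12 (0.16 ± 0.26) was higher in 2 of 6. This comparison holds the foot phalanges library of replicate 5 labelled digit V, with 1.3 CPM of Hoxd10 and 2.09 CPM of Hoxd11. The missing calls therefore do not show equal levels. Cartilage matrix genes were lower in 17 of 22 (21 adjusted over the list alone; adjusted p = 6.89e-29, and adjusted p = 0.00571 with an estimated correlation). Epyc (ENSMUSG00000019936, chromosome 10, 97644068 to 97682454), a small proteoglycan gene, was at -1.59 ± 0.18 and Col11a2 at -0.88 ± 0.11. Osteoblast genes were lower in 5 of 12 (8 adjusted over the list alone; adjusted p = 1.02e-06, and adjusted p = 0.00433 with an estimated correlation). Hypertrophic genes were lower in 4 of 16 and higher in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.000198, and adjusted p = 0.151 with an estimated correlation). Col10a1 was at -1.15 ± 0.26. The WNT antagonist gene Frzb was lower by more (-2.31 ± 0.28).

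Erythroid markers were higher in digit V in 6 of 8 genes (8 adjusted over the list alone; adjusted p = 1.46e-05, and adjusted p = 0.151 with an estimated correlation). Muscle markers were higher in 1 of 15, also adjusted over the list alone (adjusted p = 0.0151, and adjusted p = 0.579 with an estimated correlation). Of 12 epidermis markers, 2 were lower in digit V (7 adjusted over the list alone) and 1 was higher, Epcam (0.76 ± 0.23), and the list was not called (adjusted p = 0.325). The epidermal gene Krt6a had 0.77 ± 1.72 against 9.04 ± 18.3 CPM, a call lost without replicate 3 or replicate 4. It was among the 8 largest falls with Pkp1, Esrp1, Dmkn, Them5, Trim29, Dsg1b and Ap1m2. Spreads in digit III were wide (Dmkn 10.0 ± 22.05 CPM). Of the digit III libraries, hand phalanges replicate 2 (7.43 log2 CPM) and foot phalanges replicate 3 (4.6) had the highest epidermis marker means. Whether skin RNA in those libraries accounts for these falls was not tested. In all, 1450 genes differed, 587 higher and 863 lower. Without the replicate block 929 passed, with the 3 marker covariates 857, with library quality weights 3287, and without the 3 libraries with the fewest genes detected 2639. The count was 859 without replicate 3 and 938 without replicate 4.

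Matched hand and foot elements were compared within each digit. In digit I, 4263 genes differed between the phalanges (2397 higher and 1866 lower in the hand) and 2849 between the metapodials (1347 and 1502). In digit III, 40 (33 and 7) and 277 (143 and 134) differed, and in digit V, 170 (120 and 50) and 2037 (1052 and 985). Tbx5, Tbx4 and Pitx1 passed in all 6 comparisons, with Tbx5 from 3.25 ± 0.29 in digit III phalanges to 7.29 ± 0.37 in digit III metapodials. In digit III phalanges, C1qtnf2 (1.45 ± 0.29) was higher and Cd83 (-0.69 ± 0.16) lower in the hand. In digit V phalanges Steap4 (2.25 ± 0.43) was higher and the growth regulator gene Hmga2 (-0.97 ± 0.23) lower; apart from Steap4, these calls were lost under other settings. The LIM homeobox gene Isl1 had 0.027 ± 0.066 CPM in metacarpal V and 15.51 ± 4.92 CPM in metatarsal V (adjusted p = 1.73e-05). Ostn had 0.0041 ± 0.010 and 9.17 ± 4.90 CPM in the digit I metapodials (adjusted p = 3.71e-10). In digit I phalanges the epidermal genes Prr9 (103 ± 221 CPM in the hand) and Ly6d (183 ± 310 CPM) were among the genes most raised, and Ly6d was no longer called with the marker covariates. The epidermis marker mean of that group was 4.00 ± 3.36 log2 CPM in the hand and 1.06 ± 1.36 in the foot (SD, n = 6). Hoxd10 and Hoxd11 turned direction there without the 2 foot phalanges libraries of digits I and V of replicate 5 (log2 -1.81 to 0.17 and -1.91 to 0.34).

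Digit I phalanges had more genes than the phalanges of digits III and V under each setting run, but 1620 with the marker covariates and 1728 without replicate 1. The order of the metapodials turned under some settings: 136 genes differed in digit I against 773 in digit III and 1961 in digit V when only the libraries of the compared pair were fitted, and 1682 in digit I against 4494 in digit V without the 3 libraries with the fewest genes detected. Without the replicate block, 6, 15, 125 and 1277 genes passed in digit III phalanges, digit V phalanges, digit III metapodials and digit V metapodials. Without the 2 replicate 5 libraries 85 passed in digit V phalanges. Library quality weights instead raised the counts of all these digit III and V comparisons. Fitting only the libraries of the compared pair raised those of digit III and of digit V phalanges. The values are given with the processing below.

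**Figure D4:**
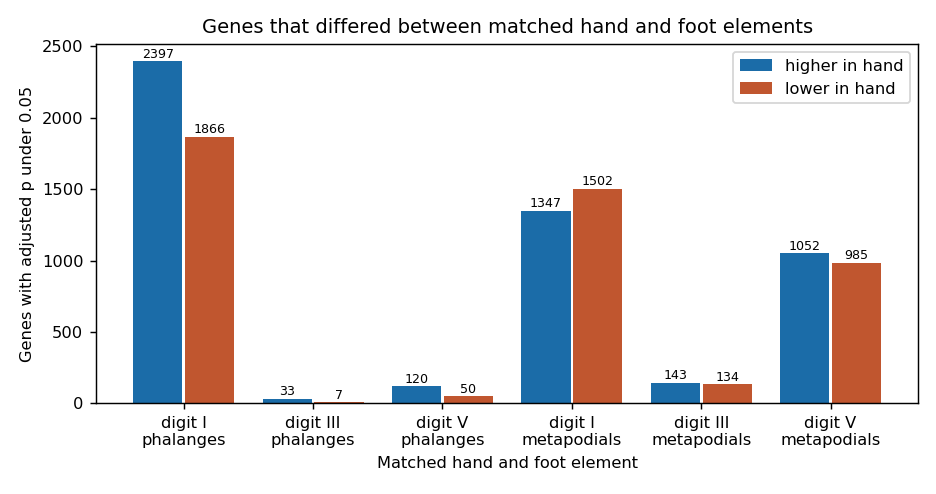
Number of genes with an adjusted p under 0.05 between the hand and the foot element of the same kind and digit (6 embryos each); blue bars are genes higher in the hand and orange bars genes lower. The bars are tallest for the digit I phalanges (2397 and 1866) and lowest for the digit III phalanges (33 and 7).

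The limb difference of digit I was tested against that of digits III and V directly, and differed in 640 genes (316 higher and 324 lower). Genes of chondrocyte hypertrophy were lower in the digit I of the hand, relative to the foot, than in the other digits. Ihh had 24.0 ± 18.9 CPM in metacarpal I and 207 ± 54.0 CPM in metatarsal I, but 137 ± 37.8 and 144 ± 22.8 CPM in the metapodials of digit III, a difference of differences of -2.14 ± 0.26 (adjusted p = 6.78e-08, 6 of 6 embryos). Of 16 hypertrophic chondrocyte genes, 10 were lower (12 adjusted over the list alone; adjusted p = 4.57e-15, and adjusted p = 0.00113 with an estimated correlation). Among them were Panx3 (-2.63 ± 0.35), Col10a1 (-2.80 ± 0.46) and the transcription factor genes Runx3 (-1.435 ± 0.183) and Runx2 (-1.01 ± 0.17). Anterior limb genes were higher in 3 of 9 (4 adjusted over the list alone; adjusted p = 0.000585, and adjusted p = 0.0053 with an estimated correlation), led by Alx4 (2.80 ± 0.60). Hoxb7 (-3.52 ± 0.61) and Gpc5 (-3.11 ± 0.57) were also lower, as was Hoxd13 (-0.53 ± 0.11). Epidermis markers moved the same way as the higher genes (1 of 12 higher, 8 adjusted over the list alone; adjusted p = 0.000328, and adjusted p = 0.361 with an estimated correlation). The count was 340 without replicate 4 and 397 without replicate 1.

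The limb difference also depended on the element in 360 genes (244 higher and 116 lower). Tbx5 differed less between the limbs in phalanges (log2 3.81 ± 0.17) than in metapodials, by -2.65 ± 0.24 (adjusted p = 6.02e-12). Gpr83 (5.44 ± 0.66) and the peptide hormone gene Uts2b (3.91 ± 0.53) showed a lower hand level in metapodials than in phalanges relative to the foot. Osteoblast and perichondrium genes were higher in 3 of 12 (8 higher and 1 lower adjusted over the list alone; adjusted p = 1.34e-08, and adjusted p = 0.000511 with an estimated correlation). Examples were Postn (1.14 ± 0.15) and Dlx5 (1.28 ± 0.19). Hypertrophic genes were higher in 4 of 16 (7 adjusted over the list alone; adjusted p = 8.52e-07, and adjusted p = 0.0313 with an estimated correlation). Without the replicate block 236 genes passed, and 188, 212 and 237 without replicates 4, 1 and 3.

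The difference between phalanges and metapodials was not the same in digit I as in digits III and V for 1230 genes (674 higher and 556 lower). Per the labels, digit I has proximal and distal phalanges only, so its pool of phalanges differs in bones from those of digits III and V. An effect of the bones pooled cannot be told apart here from one of the digit. Posterior limb genes were higher in 5 of 7 and lower in 1 (6 and 1 adjusted over the list alone; adjusted p = 1.1e-06, and adjusted p = 0.00364 with an estimated correlation). Sall1 (2.85 ± 0.28), Tbx2 (1.80 ± 0.22) and Tbx3 (1.33 ± 0.26) were higher and Hand2 was lower (-0.84 ± 0.25). Of the others counted as higher, Hoxd10 went from 1.92 to 0.83 and lost its call without the foot phalanges libraries of digits I and V of replicate 5, and Hoxd11 went from 2.69 to 1.565 and kept it. Sp9 was higher in phalanges than metapodials in digit I too (3.03 ± 0.36), but by less than elsewhere (-3.77 ± 0.49). Mstn, the growth inhibitor of skeletal muscle, was higher (5.93 ± 0.83). It was among the 5 largest rises with Isl1, Cacna1e, Msc and the muscle marker gene Myh8. Muscle markers were higher in 5 of 15 (12 adjusted over the list alone; adjusted p = 2.01e-07, and adjusted p = 0.131 with an estimated correlation). Without the replicate block 778 genes passed and with the marker covariates 782. Without replicates 4, 2 and 5 the counts were 582, 659 and 750.

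The labels gave a sex for each library, and Xist with the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were read against it. They matched in 73 of 74 libraries. The library labelled male of hand phalanges digit I replicate 6 had 696 CPM of Xist, above the 272 to 655 CPM of libraries labelled female, while no other library labelled male exceeded 0.90 CPM. The other 11 libraries of replicate 6 were labelled female and had 388 to 655 CPM. The library was kept in its group and embryo as labelled, and sex alone does not tell which female embryo a library came from.

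The 2 kits gave different levels for many genes in the digit III phalanges of replicate 2. Among 10917 genes of at least 10 CPM, 2035 were at least 2-fold higher and 774 at least 2-fold lower with the KAPA kit in both limbs, such as Col1a1 with 5880 against 1500 CPM and Hoxd11 with 112 against 40.7 CPM in the hand. The log2 difference of Tbx5 between hand and foot was 3.28 with the standard kit and 3.47 with KAPA, while that of Hoxa11 was 0.91 and -0.42. Across genes, which are not independent replicates, the hand-foot differences of the kits had a Pearson r of 0.929. With the standard kit the epidermis marker mean was 7.43 log2 CPM in this hand library and -0.903 in the foot library. The correlation therefore cannot tell limb differences from skin RNA in the hand sample. With 1 library per element and kit these are values without a replicate check.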

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

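Tests chosen only after the results were seen were those of a few genes taking most counts, of leaving out 8 libraries, and of the order of the digits by genes called, the pattern weighed for digit I was narrowed to the limb by digit I difference at that stage too, and the HoxD levels were known before the position of libraries was scored. Single libraries far from the other 5 of their group, by the gap over the range of the group, occurred in 40 of 252 sets of a measure and a group over 21 measures, or 15.9%. For normally distributed values chance marks about 1 in 20 groups. Gene levels were taken as CPM without a log scale and need not be normal. The share that chance would mark here is therefore not known. In 7 of the 40 the other 5 libraries had 0 CPM of Hoxc10 or Hoxc11, so that any count would have been marked. Without the 8 sets with at least 5 libraries at 0, 33 of 244 remained (13.5%), over measures that are not independent.

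In foot phalanges of replicate 5, the library labelled digit I had 33.8 CPM of Hoxd10, 37.0 CPM of Hoxd11 and 137 CPM of Hoxd12, against at most 1.5, 2.17 and 5.39 CPM in the other 5. The library labelled digit V had 1.3 CPM of Hoxd10 and 2.09 CPM of Hoxd11, against at least 17.8 and 27.2 CPM. On a scale from digit V (0) to digit I (1), built in the other embryos from 100 genes without the HoxD genes, the library labelled digit I stood at 0.192 (0.697 to 0.925 in the other embryos) and the one labelled digit V at 0.928 (-0.037 to 0.363). Both lie on the far side, which argues against mixed RNA and is consistent with an exchange of these 2 labels, as a hypothesis. No biological explanation was tested, the libraries were kept as labelled, and 85 genes passed in digit V phalanges without them.

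The library of metatarsal I replicate 5 had 17610 genes detected, against 22908 or more in the other 5 of its group, and with metacarpal I replicates 2 and 5 it was among the 3 libraries with the fewest. After thinning each library to 18117001 counts, the highest of these 3 had 18481 genes and the lowest of the other 69 had 19581, which argues against lower totals as the whole reason. The 10 highest genes took 5.46% to 7.53% of their counts, within the range of the others (2.57% to 12.88%) in 3 of 3, which argues against a few genes taking most counts. The other metacarpal I libraries had 22008 to 23360 genes and the other metatarsal I libraries 22908 to 23313, against a median of 23093 over all standard-kit libraries. These values argue against a difference shared by all digit I metapodials. Losses of RNA before sequencing stay open and were not tested, as does a biological difference limited to these 3 libraries.

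The difference between hand and foot varied by element in 360 genes and by digit I in 640, and that between phalanges and metapodials by digit I in 1230, each a test of the difference itself. With the 3 marker covariates 503 genes passed for limb by digit I, and 699 without the 8 libraries that stood apart, which argues against skin, muscle or blood RNA, and against those libraries, as the whole reason for that difference. Digit I phalanges had more genes than those of digits III and V with the covariates (1620 against 46 and 151) and without the 8 libraries (4928 against 183 and 400), though the covariates took their count down from 4263, so a part from skin, muscle or blood RNA stays open. Digit I metapodials had more with the covariates (2918 against 341 and 1192) but not without the 8 libraries (1886 against 829 and 4807), so their higher count may rest on those libraries. A biological difference between thumb and big toe stays open, as untested. Of 21 splits with labels reassigned within embryos, the real one included, 1 reached the real count in each. The highest of the others was 82 against 360, 7 against 640 and 653 against 1230. All labels of an embryo were reassigned at once, so real differences between groups can lower the other counts. These splits alone therefore do not exclude chance.

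Cartilage genes stood out in single libraries. Replicate 2 of metacarpal III had 28400 CPM of Col2a1 and 1400 CPM of Sox9, above the other 5 (at most 15400 and 853 CPM), and 83.9 CPM of Tbx4. Sox9 was low in metacarpal I replicate 2 (494 CPM) and high in metatarsal V replicate 5 (1020 CPM). Replicate 6 was high in Col10a1 in foot phalanges III (86.0 CPM), metatarsal III (119 CPM) and metatarsal V (42.4 CPM), and in foot phalanges III also in Ihh (265 CPM) and Col2a1 (6970 CPM).

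Limb genes stood out as well. Pitx1 was high in replicate 5 of foot phalanges I (94.2 CPM) and of metatarsal I (201 CPM) and in replicate 3 of foot phalanges III (93.9 CPM). Tbx5 was high for the foot in foot phalanges I replicate 6 (15.6 CPM) and metatarsal III replicate 1 (1.41 CPM). Hoxa11 was high in hand phalanges V replicate 6 (33.4 CPM), and Hoxd13 (311 CPM) and Hoxd11 (2.60 CPM) in metacarpal I replicate 2.

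Hoxc10 and Hoxc11 had group means of at most 0.356 and 0.179 CPM except in metatarsal V (1.498 and 0.85 CPM), and single libraries stood above the others of their group. Hoxc10 had 0.997 CPM in hand phalanges III replicate 2, 0.332 CPM in hand phalanges V replicate 3, 0.0721 CPM in metacarpal III replicate 1, 0.055 CPM in metacarpal V replicate 3 and 0.185 CPM in metatarsal I replicate 3. Hoxc11 had 0.258 CPM in foot phalanges I replicate 5, 0.898 CPM in hand phalanges I replicate 2, 0.0854 CPM in hand phalanges III replicate 2 and 0.743 CPM in metacarpal I replicate 2. It had 0.0271 CPM in metacarpal V replicate 4, 0.0265 CPM in metatarsal I replicate 3, 0.101 CPM in metatarsal III replicate 1 and 1.46 CPM in metatarsal V replicate 3.

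Marker means of other tissues stood apart in 3 libraries. Epidermis markers were high in hand phalanges III replicate 2 (mean log2 CPM 7.43, next 2.31) and metacarpal V replicate 2 (3.09, next 0.92). Muscle markers were low in foot phalanges III replicate 4 (-2.12, next -1.17).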

How the results depend on the processing

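The tests chosen only after the results were seen were those with library quality weights and those leaving out 3, 2 or 8 libraries. Of 231 counts of called genes recomputed under the 19 settings, 162 stayed within 1.5 times the first count and 69 did not. At most 2 genes of a comparison were called in the opposite direction under any setting. The hand-foot count was within 1.5 times of 6829 under each setting.

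In hand against foot, phalanges against metapodials and digit I against III, counts without the replicate block stayed within 1.5 times. Without the block, 929 genes passed in digit V against III, 6 in digit III phalanges, 15 in digit V phalanges, 125 in digit III metapodials, 1277 in digit V metapodials, 236 in limb by element and 778 in element by digit I. The cause was not tested.

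DESeq2 called 104 genes in digit III phalanges, 360 in digit V phalanges, 465 in digit III metapodials, 573 in limb by element, 1021 in limb by digit I and 1901 in element by digit I. The 3 marker covariates left 2537 genes in phalanges against metapodials, 4574 in digit I against III, 857 in digit V against III, 1620 in digit I phalanges, 1192 in digit V metapodials and 782 in element by digit I. Counts summed per embryo gave 2563 genes in digit V against III. Only the 2 groups' libraries gave 374 genes in digit III phalanges, 759 in digit V phalanges, 136 in digit I metapodials and 773 in digit III metapodials. The cause of these shifts was not tested.

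Quality weights gave 3287 genes in digit V against III, 869 in digit III phalanges, 1480 in digit V phalanges, 1678 in digit III metapodials, 4353 in digit V metapodials and 735 in limb by element. Without the 3 libraries with the fewest genes, 2639 passed in digit V against III, 6441 in digit I phalanges, 170 in digit III phalanges, 568 in digit V phalanges, 1682 in digit I metapodials, 702 in digit III metapodials and 4494 in digit V metapodials. Without the foot phalanges libraries I and V of replicate 5, 85 passed in digit V phalanges. Without the 8 libraries, 2296 passed in digit V against III, 183 in digit III phalanges, 400 in digit V phalanges, 1886 in digit I metapodials, 829 in digit III metapodials and 4807 in digit V metapodials.

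Leaving out each embryo gave 5041 to 7193 genes in hand against foot, 8076 to 9180 in phalanges against metapodials, 7340 to 8971 in digit I against III and 859 to 1442 in digit V against III. In the matched phalanges it gave 1728 to 4259 in digit I, 9 to 47 in digit III and 53 to 207 in digit V, and in the metapodials 1900 to 2679, 125 to 345 and 797 to 2392. The differences of differences gave 188 to 331 for limb by element, 340 to 547 for limb by digit I and 582 to 1190 for element by digit I. Digit III phalanges had 9, 25 and 12 genes without replicates 1, 3 and 4. Digit V phalanges had 71, 65, 53 and 103 without replicates 1, 3, 4 and 6. Digit III metapodials had 140, 125 and 150 without replicates 1, 4 and 6, and digit V metapodials 1281, 1147, 797 and 1259 without replicates 1, 2, 3 and 4.

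Of 388 results of named genes, 254 kept their direction and their call under every setting run, 134 lost the call under at least 1, and 7 reversed under at least 1. Between hand and foot, Alx4 turned to 0.53 with summed counts. Between phalanges and metapodials, summed counts turned Hoxc10 to -0.73, Tbx5 to -0.016 and Hoxd10 to -0.003, quality weights turned Hoxc10 to -0.026, and the covariates turned Myod1 to 0.585, which follows from their construction since Myod1 is one of the muscle markers. In digit I phalanges, Hoxd10 turned to 0.17 and Hoxd11 to 0.34 without the pair of replicate 5, to 0.13 and 0.002 without the 8 libraries, and to 0.125 and 0.332 without replicate 5 (lowest with an embryo left out -2.338 and -2.356, without replicate 2). Of 84 list tests in the main comparisons 31 were called, 33 without the block, 32 with a prior count of 0.5 and 13 with an estimated correlation. On simulated data for the digit III phalanges 34.3% of genes changed by a log2 fold of 1 were recovered, so a gene not called there may still differ; the other matched comparisons were not simulated.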

Other observations

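The look at mast cell genes was chosen only after the named genes were seen; the reassignments of labels were planned. A list of 10 mast cell genes was written because the protease genes Cma1, Tpsb2 and Tpsab1 were among the genes higher in digit I, so these 3 members were picked from the same libraries and no test of the list is given. Of the 10 genes 7 were tested one by one, and no other list holds them. Against digit III, 6 of 7 were higher in digit I, with a median log2 fold change of 2.60, and 5 of 7 in digit V, with a median of 1.66. Cpa3 rose by 2.31 ± 0.37 in digit I and by 1.66 ± 0.36 in digit V, Hdc, the enzyme gene of histamine synthesis, by 2.00 ± 0.38 in digit I, and Cma1, with a mean of 25.6 CPM in digit I, by 2.80 ± 0.37 there. Both comparisons share the libraries of digit III.

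The mean log2 CPM of the mast cell genes varied over the elements, with wide spreads that overlapped between many groups and no test run. The range of metacarpal III (-2.689 to -0.86) lay wholly below those of metatarsal I (lowest 0.018), metatarsal V, metacarpal V and the phalanges of digit I. It was 2.96 ± 1.68 (SD, n = 6) in metatarsal I, 1.497 ± 1.51 in metatarsal V, 1.23 ± 0.78 in hand phalanges of digit I, 0.84 ± 1.49 in foot phalanges of digit I, 0.705 ± 1.59 in hand phalanges of digit V and 0.64 ± 2.11 in metacarpal I. The lowest of the 12 groups were metacarpal III at -1.43 ± 0.74 and metatarsal III at -0.80 ± 0.76. Between hand and foot 1 of 7 genes was lower, Ms4a2, and between phalanges and metapodials 1 was higher, Mcpt4.

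Group labels were reassigned within embryos, which gives 21 splits with the real one for each comparison. In each comparison the real split alone, 1 of 21, reached its count, the smallest share that 21 splits can give. In the main comparisons and the differences of differences all labels of an embryo were reassigned at once. In the matched comparisons hand and foot were exchanged in all elements of some embryos. Real differences between groups then enter the variation within groups and can lower the other counts, so these splits alone do not exclude chance. The real count and the highest of the others were 6829 and 2 for hand against foot, 9301 and 2 for phalanges against metapodials, 9066 and 0 for digit I against III, and 1450 and 210 for digit V against III. In the matched phalanges they were 4263 and 1694 in digit I, 40 and 3 in digit III and 170 and 1 in digit V. In the matched metapodials they were 2849 and 1127 in digit I, 277 and 0 in digit III and 2037 and 8 in digit V. For gene lists they were 31 and 18, with a median of 13, which shows that the preset correlation calls lists without a group difference.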
